A study of Mus musculus with 16 samples.

How the data were processed

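Total RNA from the hypothalamus of male mice aged 6 weeks was measured on 16 arrays, 4 biological replicates in each of 4 groups: Mecp2-null and wild type mice on C57BL/6J, and MECP2-transgenic and wild type mice on FVB. Per the labels, RNA was extracted with TRIzol, treated with DNase, cleaned on columns and labelled with biotin. Per the submitters' processing notes, the software used was GCOS 1.1. The method of background correction, normalization and probe set summary is not given in the sources used here. The values of the deposited table were treated as log2 values made by the authors, since they run from 1.2 to 14.38 with 2 decimals. The base of the logarithm is inferred from that range, and if it were not 2, every fold change here would differ. There were 1201338 probe sets, with array medians from 4.61 to 4.68 and interquartile ranges from 3.31 to 3.41. Since both ranges lay within the limit of 0.1 that was set beforehand, the second only just, the values were used as deposited.

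Of the probe sets, 321030 carried a gene annotation, 313617 of them with 1 symbol. The 7413 with several symbols were left out, and 880308 named no gene. The 22359 symbols were updated against a current mouse gene table of assembly GRCm38.p6 (18040 current, 4256 replaced by the only current symbol that lists them as a synonym, 63 unmatched), which left 22165 genes. That table was used for names, gene order and gene lengths only, and no coordinates are reported. Mecp2 was not named by any probe set in the annotation and was not analysed here, so the labels were not checked against its level. Probe sets with a mean over all arrays above 4.62, the median of all probe sets, were kept (240645). Genes with at least 2 kept probe sets were summarised by median polish, which gave 17728 genes with a median of 10 and at most 161 probe sets each. A summary over exons does not separate transcripts, and a gene whose signal lies near the dim bound is measured with less precision. Correlations between arrays were 0.947 to 0.99.

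Groups were compared in 1 limma fit of all 16 arrays with 4 group means (limma 3.58.1 in R 4.3.3, lmFit, eBayes with trend), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The contrasts were each mutant against the wild type of its strain, the difference between those effects, and FVB against C57BL/6J wild type. A gene is called when its adjusted p is under 0.05. In a self-test on simulated data of 17728 genes with 200 changed and independent noise, the fit recovered 57% of changes of 0.5 and 97% of changes of 1 in the Mecp2-null comparison, with 2 false calls, and 45% and 94% in the transgenic comparison, with 8 false calls. It made 0 calls in an unchanged comparison. The simulated noise had the same spread in every group, so the results of the 2 comparisons differed by random draw alone. The self-test thus does not cover a group whose arrays vary more than the others, as the FVB wild type arrays did. With the neuropeptide list shifted by -0.2, camera called that list and 1 other list that shares no gene with it, a false call.

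Gene lists (32, of 803 genes, of which 90 were not tested) were fixed before the data were examined. They cover genes named by the study, earlier candidate targets of MeCP2, neuropeptides, peptide and hormone receptors, the GABA, glutamate and monoamine systems, vesicle release, synaptic adhesion, ion channels, immediate early genes, CREB and calcium signalling, glucocorticoid response, creatine metabolism, the circadian clock, chromatin corepressors, oxidative phosphorylation, ribosomal proteins, cholesterol synthesis, splicing, hypothalamic transcription factors, and markers of astrocytes, oligodendrocytes and their precursors, microglia, endothelium, ependyma, pituitary, neighbouring brain tissue, blood, stress and interferon response. The 31 lists with at least 4 genes tested went into limma camera with a correlation of 0.01, adjusted over lists, with an estimated correlation and limma fry beside it. Camera compares a list with all other genes, so its direction can differ from the sign of the list's median. The median log2 change of all genes was -0.04 in Mecp2-null and 0.05 in transgenic mice. Genes longer than 100 kb, from gene start to gene end, were compared with the others by medians.

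Named genes followed a rule written before the data were examined: in each genotype comparison up to 10 higher and 10 lower genes of largest change among those called whose 4 mutant arrays all lay beyond the 4 wild type arrays, up to 4 members of each list with the smallest unadjusted p, up to 10 genes called in both with opposite sign, up to 5 each way for the difference and 3 each way for the wild types, and all genes named by the study. Clone and predicted names were passed over. Nts, Gal, Npy, Avp and Glul are outside the rule and were named after their values were seen.

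Alternatives chosen before the data were examined were quantile normalization, no filter and a stricter filter on dim probe sets (above 6.43), the mean in place of median polish, at least 4 probe sets per gene, a fit of the 8 arrays of the strain only, the replicate number as a block, array weights, each array left out in turn, an estimated correlation in camera, and a length bound of 50 kb. Another 4 were added after the data were seen: centring each array on the median of its gene values, cyclic loess over gene values, leaving out FVB wild type arrays 3 and 4, and a thalamic marker score as a covariate. Chance was judged by splitting the 8 arrays of a strain into 4 and 4 in all 35 ways, and by 100 draws of such splits in both strains. Tables were handled with data.table (version 1.17.8) and figures drawn with matplotlib 3.10.9 in Python 3.11.15.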

Results

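Gene expression was measured in the hypothalamus of male mice aged 6 weeks, on 16 arrays of total RNA in 4 groups of 4. MeCP2 is a nuclear protein that binds methylated DNA. Its loss causes Rett syndrome in humans, and extra copies of its gene cause a separate neurological disorder. Mecp2-null males and wild type males were on the C57BL/6J background, and males carrying a MECP2 transgene and their wild type controls were on the FVB background. The arrays carried 1201338 probe sets, and 17728 genes named by the annotation passed the filter on dim probe sets and were tested. The replicates are labelled biological. With 4 arrays per group, the number of arrays limits the precision. The level of Mecp2 itself was not analysed here, so the genotypes are those of the labels. Each mutant was compared with the wild type of its own strain, to ask which genes changed with loss and with gain of MeCP2.

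Loss of Mecp2 lowered the expression of several neuropeptide and receptor genes. The kappa opioid receptor gene Oprk1 fell from 6.69 ± 0.15 in wild type to 5.84 ± 0.18 in Mecp2-null hypothalamus (log2 value, mean ± SD, n = 4), which was 1.8-fold lower, with a limma adjusted p of 0.00417. Hcrtr1, a receptor for orexin, was also 1.8-fold lower (adjusted p = 0.0104), and Nxph4, which encodes a secreted relative of the neurexin ligands, fell by 1.01 on the log2 scale with a standard error of 0.13. Tac1, the precursor of substance P, dropped by 0.77 (SE 0.11), and Adcyap1, which encodes the neuropeptide PACAP, dropped by 0.69 (SE 0.13). Fewer named genes rose, among them the zinc finger transcription factor gene Rreb1, from 8.2 ± 0.13 to 8.85 ± 0.11 (log2 change 0.64, SE 0.09, adjusted p = 0.00447).

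In all, 36 genes differed between Mecp2-null and wild type mice at an adjusted p under 0.05, 9 of them higher and 27 lower, by 1.28-fold to 2.03-fold. At an unadjusted p under 0.05 there were 1250 genes. The other named genes that rose included the axon guidance gene Slit3 (log2 change 0.63), the heparan sulfate sulfotransferase gene Hs6st3 (0.63), and the cell adhesion genes Flrt3 (0.62) and Sdk1 (0.56). Irak1, which encodes a kinase of innate immune signalling, rose by 0.52 on the log2 scale, the transcription factor gene Mef2c by 0.49, the IP3 receptor gene Itpr1 by 0.46 and the phospholipase C gene Plch2 by 0.36. Avpr1a, a vasopressin receptor gene, was 1.57-fold lower (5.11 ± 0.16 against 5.75 ± 0.04), Rab26, which encodes a small GTPase of secretory vesicles, was 1.59-fold lower, and so was the sperm fibre gene Odf4. The axonemal dynein genes Dnah7a and Dnah7b were 1.72-fold and 1.61-fold lower, but they are near-identical copies whose probes may share signal, so their separate values are uncertain. In each of these genes all 4 mutant arrays lay beyond all 4 wild type arrays.

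**Figure D1:**
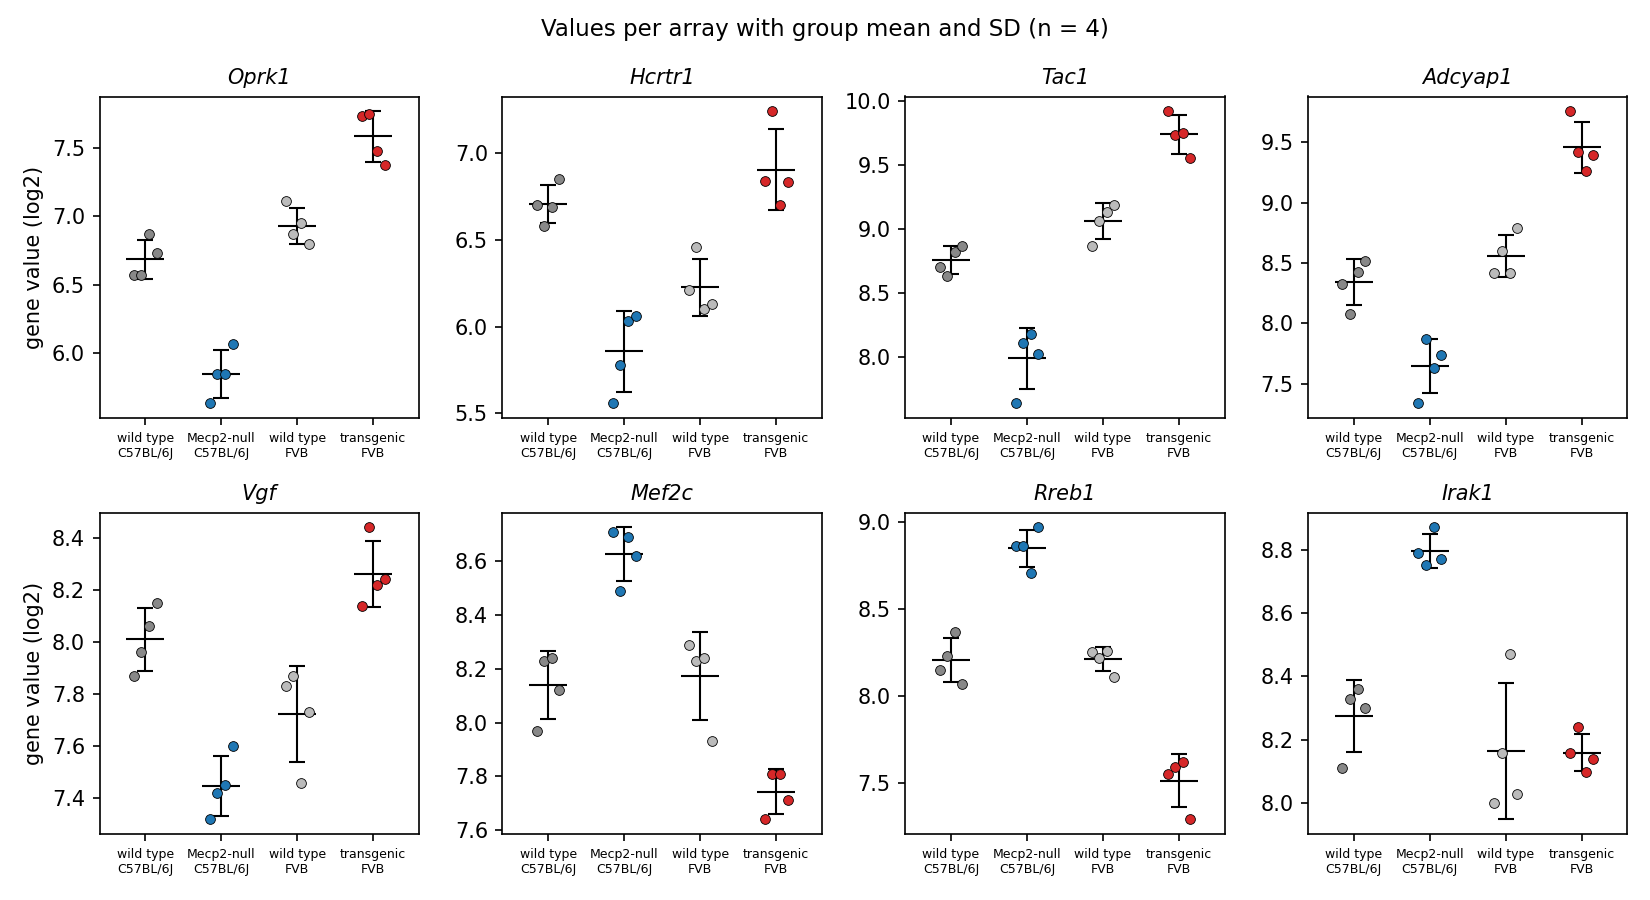
Log2 gene values (vertical axes) of 8 genes on each array, by group (horizontal axes), with the group mean and SD as black bars (n = 4). Oprk1, Hcrtr1, Tac1, Adcyap1 and Vgf lie below the wild type in the Mecp2-null and above it in the transgenic arrays, Mef2c and Rreb1 lie the other way round, and Irak1 differs in the Mecp2-null only, at 8.79 ± 0.05 against 8.27 ± 0.11.

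Of 46 hypothalamic neuropeptide and peptide-processing genes, 3 fell in Mecp2-null mice (Tac1, Adcyap1 and Vgf, the last by 0.56, SE 0.1, adjusted p = 0.0271) and 43 did not pass, while 8 were lower and 0 higher when adjusted over the list alone. As a group they stood lower than the other genes (limma camera, adjusted p = 0.000767), with an adjusted p of 0.171 with an estimated correlation. Of 44 peptide and hormone receptor genes, 3 fell (Hcrtr1, Oprk1 and Avpr1a) and 41 did not pass, with 6 lower and 2 higher when adjusted over the list alone. Their camera adjusted p was 0.00171, and 0.383 with an estimated correlation. The call of Avpr1a ended with the mean in place of median polish (-0.51, adjusted p = 0.229). Among 8 markers of oligodendrocyte precursor cells the median log2 change was -0.29, and 4 were lower when adjusted over the list alone (the same 4 at an unadjusted p under 0.05) but none over all genes. This list stood lower by camera with an adjusted p of 0.000767, and of 0.252 with an estimated correlation. Genes of cholesterol synthesis were below 0 in 19 of 20 members (median -0.11, camera adjusted p = 0.00429, adjusted p = 0.541 with an estimated correlation). The GABA system genes (18 tested, 2 lower when adjusted over the list alone, with Gad2 at -0.48 and an all-gene adjusted p of 0.0871) had a camera adjusted p of 0.0496, and 0.61 with an estimated correlation. This last call ended after centring each array (0.092), after cyclic loess (0.119) and without FVB wild type arrays 3 and 4 (0.0642).

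Other lists stood higher than the remaining genes in Mecp2-null mice, although no member passed over all genes in the deposited scaling. They were 21 circadian clock genes (median 0.06, camera adjusted p = 0.00067, adjusted p = 0.333 with an estimated correlation), 33 ion channel genes (median 0.08, 0.00429, adjusted p = 0.61 with an estimated correlation) and 26 synaptic adhesion and scaffold genes (median 0.06, 0.0107, adjusted p = 0.61 with an estimated correlation). When adjusted over the list alone, 1 clock gene was higher, 1 ion channel gene was lower and 0 adhesion genes passed. After centring, and after cyclic loess, 1 clock gene and 1 marker of thalamus, striatum and cortex were higher over all genes. Both lists hold Rora, so these counts may be of the same gene. Markers of neighbouring tissue stood higher as lists. All 6 pituitary markers were above 0 (median 0.21, camera adjusted p = 0.00429, adjusted p = 0.171 with an estimated correlation). The 16 markers of thalamus, striatum and cortex had a median of 0.11 (camera adjusted p = 0.0107, adjusted p = 0.171 with an estimated correlation), with 1 higher when adjusted over the list alone. Stress and chaperone genes were listed beforehand as a possible sign of stress or RNA quality, but RNA quality itself was not analysed here. They had a median of -0.15 with all 14 below 0 (camera adjusted p = 0.0107, adjusted p = 0.61 with an estimated correlation), and Ddit3 alone among them fell, by 0.6. Ddit3 did not pass after centring (0.0623), with a stricter filter on dim probe sets (0.23) or with the mean in place of median polish (0.2).

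Of the 7 tested genes that were chosen by the study on these samples, and so are not independent evidence, Oprk1 fell and Mef2c rose in Mecp2-null mice and 5 did not pass, with 2 higher and 3 lower when adjusted over the list alone. The list did not pass by camera (adjusted p = 0.202). The changes that did not pass over all genes were -0.47 for Sst (adjusted p = 0.138, but 0.0451 in a fit of the 8 C57BL/6J arrays and 0.0119 with array weights), -0.46 for Gamt (0.389, but 0.0339 with array weights), -0.14 for Creb1, -0.09 for Gprin1 and 0.28 for Rbfox1. Of 31 lists tested, 11 passed by camera in this comparison, 5 higher and 6 lower. With an estimated correlation camera called 0 in either genotype comparison (4 lists had an unadjusted p under 0.05 in Mecp2-null and 3 in MECP2-transgenic mice), while limma's fry called 1 in Mecp2-null and 7 in MECP2-transgenic mice.

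The count for Mecp2-null mice depended on the fit and on single arrays. It was 84 (19 higher, 65 lower) in a fit of the 8 C57BL/6J arrays. With array weights it was 259 (60 higher, 199 lower), and without FVB wild type arrays 3 and 4 it was 59. It was 8 without null array 1 or C57BL/6J wild type array 4, 12 without null array 2, 13 without null array 3 or wild type array 3, 21 without wild type array 1 and 22 without null array 4. The calls of Oprk1, Nxph4, Tac1, Rreb1, Hs6st3 and Sdk1 passed whichever array was left out, and that of Hcrtr1 ended without null array 1 (0.0503) or wild type array 4 (0.0569). Slit3 and Avpr1a ended without null array 1 or 3 or wild type array 4 (up to 0.0642 and 0.0746), and Dnah7b and Odf4 without null array 1 or 2 or wild type array 3 or 4 (up to 0.0833 and 0.0965). Dnah7a and Zfp57 ended without null array 1, 2 or 3 or wild type array 3 or 4 (up to 0.117 and 0.105), and Vgf also without wild type array 2 (up to 0.155). Adcyap1, Itpr1 and Rab26 ended without any C57BL/6J array but wild type array 2 (up to 0.18, 0.159 and 0.114), and Flrt3 without any but wild type array 3 (up to 0.131). Irak1, Mef2c, Ddit3, Hnmt and Plch2 ended without any of the 8 C57BL/6J arrays (up to 0.114, 0.154, 0.134, 0.18 and 0.2), the last 3 also without some FVB arrays. Without a filter on dim probe sets the calls of Flrt3 (0.0993), Mef2c (0.052), Dnah7a (0.105) and Odf4 (0.116) ended. With the stricter filter that of Plch2 (0.0525) ended, with the mean in place of median polish those of Mef2c (0.0515), Plch2 (0.0677) and Hnmt (0.0677), and after centring that of Zfp57 (0.0589). The number of lists called was 7 without null array 1. The share of higher genes moved with the scaling, from 9 higher and 27 lower as deposited to 19 and 19 after centring each array on the median of its gene values (28 genes shared) and 25 and 25 after cyclic loess (33 shared).

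Several of the same neuropeptide and receptor genes were higher in transgenic than in wild type FVB mice. The adjusted p-values below rest on a variance shared with the C57BL/6J arrays. In a fit of the 8 FVB arrays only, Adcyap1, Agrp, Prph and Rreb1 passed and Oprk1 and Itpr1 did not. Oprk1 rose from 6.93 ± 0.13 in FVB wild type to 7.59 ± 0.19 in transgenic hypothalamus (1.57-fold higher, n = 4, limma adjusted p = 0.00836), and Adcyap1 rose from 8.56 ± 0.17 to 9.46 ± 0.21 (1.87-fold, adjusted p = 0.00264). Agrp, which encodes the appetite-stimulating agouti-related peptide of the arcuate nucleus, rose 2-fold (log2 change 1, SE 0.14, adjusted p = 0.00198), and Prph, the neuronal intermediate filament gene peripherin, rose 2.11-fold from 6.49 ± 0.1 to 7.57 ± 0.17. Rreb1 fell by 0.69 (SE 0.09, adjusted p = 0.00137) and the IP3 receptor gene Itpr1 fell by 0.61 (adjusted p = 0.00198).

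At an adjusted p under 0.05, 513 genes differed between transgenic and wild type FVB mice, 448 higher and 65 lower, by 1.15-fold to 3.1-fold, with a median of 1.37-fold. At an unadjusted p under 0.05 there were 3453. The largest rises among named genes were in the zinc finger gene Zfp874a (log2 change 1.63, SE 0.29), whose FVB wild type arrays spread widely (5.43 ± 0.84) and whose call ended with a stricter filter on dim probe sets (0.39, adjusted p = 0.116), and in Ssxb9 (1.42), whose call ended without a filter (0.46, adjusted p = 0.126). Pgr15l rose by 1, the growth factor-binding protein gene Igfbp2 by 0.98, the matrix gene Efemp1 by 0.96, the neuropeptide B and W receptor gene Npbwr1 by 0.94, and the complement gene C1qc by 0.94. Gamt, an enzyme of creatine synthesis, rose by 0.94 (SE 0.15), from 7.25 ± 0.37 in wild type to 8.19 ± 0.22 in transgenic mice. Among the genes that fell were the latrophilin gene Adgrl2 (log2 change -0.7), the RNA-binding protein gene Rbms3 (-0.69), the zinc finger gene Zfp385b (-0.64), the teneurin gene Odz3 (-0.63) and Fhdc1 (-0.58), with Iyd, the iodotyrosine deiodinase (-0.78), Mospd4 (-0.65) and the immune receptor gene Cd27 (-0.64), these last 3 not passing after cyclic loess. Without a filter on dim probe sets Cd27 was at -0.17 (adjusted p = 0.595) and Mospd4 at -0.43 (0.254), and Iyd did not pass either (0.0536).

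The balance of higher and lower genes in transgenic mice depended on how the arrays were scaled. It was 448 higher and 65 lower in the values as deposited, 169 higher and 199 lower after centring each array on the median of its gene values (234 genes shared with the deposited scaling), and 197 higher and 184 lower after cyclic loess (252 shared). Centring moved the median log2 change of all genes in this comparison from 0.05 to -0.05, in Mecp2-null mice from -0.04 to 0.03, and no gene called higher as deposited was called lower afterwards. The calls of Agrp, Adcyap1, Tac1, Oprk1, Hcrtr1, Vgf, Prph, Gamt, C1qc, Rreb1, Itpr1 and Mef2c passed under both scalings.

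**Figure D2:**
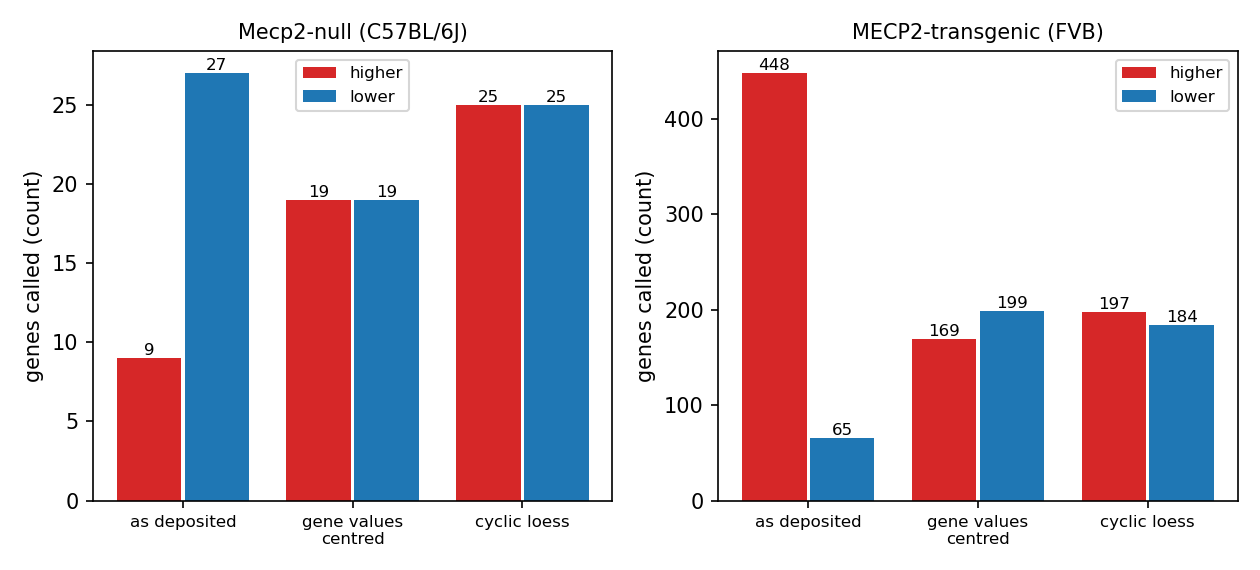
Genes called higher (red) and lower (blue) than wild type at an adjusted p under 0.05 (vertical axes, counts), for Mecp2-null and MECP2-transgenic mice, in values as deposited, centred per array and after cyclic loess (horizontal axes). In transgenic mice the 448 higher and 65 lower genes became 169 and 199 after centring and 197 and 184 after cyclic loess.

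Of 46 neuropeptide genes 9 rose in transgenic mice, 0 fell and 37 did not pass, with 12 higher when adjusted over the list alone. Apart from Agrp and Adcyap1 these were Tac1 (0.67) and Vgf (0.54), and, named after their values were seen, Nts, the neurotensin gene (0.87), Gal, the galanin gene (0.76), Npy, the neuropeptide Y gene (0.61), Avp, the vasopressin gene (0.6), and the enkephalin gene Penk (0.48). The calls of Gal, Avp and Penk ended under both scalings and that of Npy after cyclic loess, which left 6 called after centring and 5 after loess. There were 8 higher and 1 lower without FVB wild type arrays 3 and 4. The list stood higher by camera (adjusted p = 0.00315), with an adjusted p of 0.313 with an estimated correlation. Among 44 receptor genes Hcrtr1 (0.68), Oprk1 (0.65) and the thyroid hormone receptor gene Thra (0.39) rose and the growth factor receptor gene Igf1r fell by 0.36, with 7 higher and 1 lower when adjusted over the list alone. That list did not pass by camera (adjusted p = 0.0721).

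Markers of oligodendrocyte precursors and of microglia stood higher in the same comparison. Of 8 markers of oligodendrocyte precursors, C1ql1 (0.8), Gpr17 (0.73) and Vcan (0.44) rose, 5 did not pass, and 7 were higher when adjusted over the list alone (camera adjusted p = 0.000355, adjusted p = 0.313 with an estimated correlation). The call of Vcan ended under both scalings. All 15 microglial markers were above 0 (median 0.33), of which the complement genes C1qc and C1qa (0.44) rose, the second not after cyclic loess. There were 6 higher microglial markers when adjusted over the list alone (camera adjusted p = 0.00274, adjusted p = 0.448 with an estimated correlation). The microglial median was 0.16 without FVB wild type arrays 3 and 4 (camera adjusted p = 0.0215), and there C1qa (0.0673) and Vcan (0.121) did not pass. Endothelial markers stood lower (16 tested, median -0.05, camera adjusted p = 0.0166, adjusted p = 0.696 with an estimated correlation), with no member passing over all genes or over the list alone and 2 lower at an unadjusted p under 0.05. After centring, and after cyclic loess, 2 endothelial markers were lower over all genes. Among 16 markers of thalamus, striatum and cortex, Plekhg1 fell by 0.57 and Rora, a nuclear receptor of the circadian clock, by 0.39, with 4 lower when adjusted over the list alone and 4 over all genes under either other scaling (camera adjusted p = 0.00849, adjusted p = 0.187 with an estimated correlation).

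Ribosomal protein genes stood higher (48 of 51 above 0, median 0.25, camera adjusted p = 0.00274, adjusted p = 0.745 with an estimated correlation), as did genes of oxidative phosphorylation (40 of 44 above 0, median 0.22, camera adjusted p = 0.00502, adjusted p = 0.739 with an estimated correlation). Of the first only Rplp1 passed over all genes, in the deposited scaling and not after centring or loess, and adjusted over the list alone the counts were 1 and 0, against 12 and 12 at an unadjusted p under 0.05. Without FVB wild type arrays 3 and 4, 10 ribosomal and 5 oxidative phosphorylation genes were higher over all genes. Stress and chaperone genes, which are no direct measure of RNA quality, had a median of 0.27 and stood higher beside them (camera adjusted p = 0.00274, adjusted p = 0.696 with an estimated correlation). Of these Ddit3 and the chaperone gene Dnajb1 (both 0.46) were higher, under neither other scaling, and 5 were higher when adjusted over the list alone. Cholesterol synthesis genes had 19 of 20 members above 0, and the sterol reductase gene Tm7sf2 rose by 0.45 in the deposited scaling alone. There were 4 higher when adjusted over the list alone (camera adjusted p = 0.0103, adjusted p = 0.696 with an estimated correlation). Without FVB wild type arrays 3 and 4 this list did not pass (0.0725).

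Ion channel genes stood lower as a list (33 tested, median -0.07, camera adjusted p = 0.0103, adjusted p = 0.739 with an estimated correlation), yet the members that passed in the deposited values were the calcium channel genes Cacna1g (0.39) and Cacna1b (0.26), both higher, with 2 higher and 2 lower when adjusted over the list alone. After centring 0 were higher and 3 lower, and after cyclic loess 0 were higher and 4 lower. Without FVB wild type arrays 3 and 4, 1 was higher and 4 lower. Circadian clock genes also stood lower (21 tested, median -0.03, camera adjusted p = 0.0191, adjusted p = 0.696 with an estimated correlation), with Rora lower and the kinase gene Csnk1e higher (0.29), the latter under neither other scaling, and the same counts of 1 each when adjusted over the list alone. Of the 7 genes chosen by the study on these samples, not independent evidence, Gamt, Oprk1 and Gprin1 (0.4) rose, Mef2c fell by 0.43 and 3 did not pass, namely Sst at 0.38 (adjusted p = 0.0775, but 0.00991 with the mean in place of median polish), Creb1 at 0.19 and Rbfox1 at -0.19. With 4 higher and 1 lower when adjusted over the list alone, the list did not pass by camera (adjusted p = 0.0749, and 0.0306 after centring), and the call of Gprin1 ended under both scalings. In the deposited scaling the adjusted p of this list with an estimated correlation was 0.696. In all, 11 of 31 lists passed by camera, 7 higher and 4 lower.

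The transgenic count moved widely with the arrays used. It was 1390 without FVB wild type array 4, and 994 without FVB wild type arrays 3 and 4, which had the lowest weights of all arrays (0.315 and 0.377). It was 126 without transgenic array 2, 152 without transgenic array 1, 191 without FVB wild type array 1, 220 without transgenic array 4, 341 without null array 2 and 337 without C57BL/6J wild type array 4. With array weights it was 1056. A fit of the 8 FVB arrays only called 30, with Agrp, Adcyap1, Tac1, Prph, C1qc and Rreb1 among them and Oprk1, Hcrtr1, Vgf, Gamt, Mef2c and Itpr1 not (adjusted p from 0.0613 to 0.145). The fit of all arrays shares its variance with the C57BL/6J arrays, which correlated more closely within groups. Its adjusted p-values in the transgenic comparison may therefore be too small. Of all 35 ways to split the 8 FVB arrays into 4 and 4, 4 called at least as many genes as the genotypes did, the genotypes included, and the largest count was 1601. Single calls ended without transgenic array 2 (Gpr17, 0.0578, and Hnmt, 0.056), without transgenic array 1 or 2 (Gprin1, C1qa and Sdk1, up to 0.0832, 0.0768 and 0.0797), or without either of these or wild type array 1 (Cacna1g, up to 0.0678). Nts ended without wild type array 1 or transgenic array 1, 2 or 4 (up to 0.0809), Npy also without wild type array 3 (up to 0.0876), Mef2c without wild type array 1 or transgenic array 1 or 4 (up to 0.0773), and Igf1r also without wild type array 2 (up to 0.0783). Of the others named, Flrt3, Odf4, Cd27, Fhdc1, Iyd, Vcan, Ddit3, Dnajb1, Tm7sf2, Rplp1, Mospd4, Nxph4, Avp, Csnk1e, Cacna1b, Penk and Gal ended without any of 5 to 14 arrays in turn (up to 0.151). Other choices of processing ended calls too. After quantile normalization they were those of Nxph4 (0.057), Mospd4 (0.0519), Penk (0.0547), Dnajb1 (0.0505), Gal (0.0608) and Avp (0.059). Without a filter on dim probe sets they were those of Gal (log2 change 0.5, adjusted p = 0.182), Avp (0.4, adjusted p = 0.159), Flrt3 and Penk, with those named above. With the stricter filter they were those of Dnah7a, Nts (log2 change 0.54, adjusted p = 0.0534), Vcan, Ddit3 and Penk. With the mean in place of median polish they were those of Npy, Flrt3, Cd27, Penk, Ddit3, Dnajb1, Cacna1b and Rplp1. With a thalamic marker score as a covariate, the transgenic calls of Flrt3, Sdk1, Nxph4, Odf4, Iyd, Mospd4, Cd27, Fhdc1, Gprin1, Igf1r, Rora, Ddit3, Rplp1, Gal, Npy and Avp ended (adjusted p from 0.0511 to 0.127), as did that of Ddit3 in Mecp2-null mice (0.0527).

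Genes called in both comparisons changed in opposite directions with loss and gain of MeCP2. Of the 30 genes called in both comparisons, 23 were lower in Mecp2-null and higher in transgenic mice, 7 were higher in Mecp2-null and lower in transgenic mice, and 0 had the same sign. Independent lists of these sizes would share 0.682 and 0.033 genes in those directions, and 0.227 and 0.099 with the same sign. These numbers are not a chance level, since both comparisons share each gene's variance estimate and genes vary together. Adcyap1 (log2 change -0.69 in Mecp2-null and 0.9 in transgenic mice), Rab26 (-0.67 and 0.91), Dnah7a (-0.79 and 0.76), Hcrtr1 (-0.85 and 0.68), Tac1 (-0.77 and 0.67), Oprk1 (-0.84 and 0.65), the histamine-degrading enzyme gene Hnmt (-0.59 and 0.56) and the imprinting regulator gene Zfp57 (-0.56 and 0.67) were among the first, and Rreb1 (0.64 and -0.69), Slit3 (0.63 and -0.51), Hs6st3 (0.63 and -0.5), Flrt3 (0.62 and -0.47) and Mef2c (0.49 and -0.43) among the second. Nxph4 was called in both as deposited (-1.01 and 0.52), but its transgenic call ended under both scalings (adjusted p = 0.131 and 0.118).

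All 36 genes called in Mecp2-null mice had the opposite sign in transgenic mice, as did 489 of the 513 genes called in transgenic mice (95.3%) and 69.6% of all genes tested. Across genes, which are not independent replicates, the log2 changes of the comparisons had a Pearson r of -0.48, a Spearman rho of -0.47 and a covariance of -0.0147. No control array was shared between them. The 6 genes called in Mecp2-null and not in transgenic mice included Irak1, which differed between the genotype effects (-0.01 in transgenic mice, test of the difference, adjusted p = 0.033), Avpr1a (0.23 in transgenic mice, difference adjusted p = 0.00304) and Plch2 (-0.09, difference adjusted p = 0.0147). A score made of the 36 genes called in C57BL/6J mice, each signed by its change there, was measured on the FVB arrays, which entered the choice of genes through the filter on dim probe sets, the gene summary and the pooled variance, but not through the contrast. This test was chosen after the opposite changes were seen. The score was -0.26 ± 0.04 in transgenic and 0.26 ± 0.04 in wild type mice, with all 4 transgenic arrays below all 4 wild type arrays (two-sided exact permutation p = 0.0286, the smallest that 70 splits allow). The score of the 513 genes called in FVB mice was -0.11 ± 0.05 in Mecp2-null and 0.11 ± 0.05 in C57BL/6J wild type mice (exact permutation p = 0.0286, n = 4). In each alternative fit the scores were made anew from the genes called in that fit, so their genes changed as well. Without FVB wild type arrays 3 and 4 the scores held 59 and 994 genes. The first difference was then -0.42 in place of -0.52 (exact permutation p = 0.0667, the smallest that 15 splits allow). The second was -0.14 in place of -0.22. With single arrays left out the differences ran from -0.64 to -0.48 (8 to 44 genes) and from -0.32 to -0.15 (126 to 1390 genes). The number of genes called in both was 7 without null array 1 or C57BL/6J wild type array 4, 10 without null array 2, 11 without wild type array 3, 12 without null array 3, and 19 without null array 4 or transgenic array 2.

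**Figure D3:**
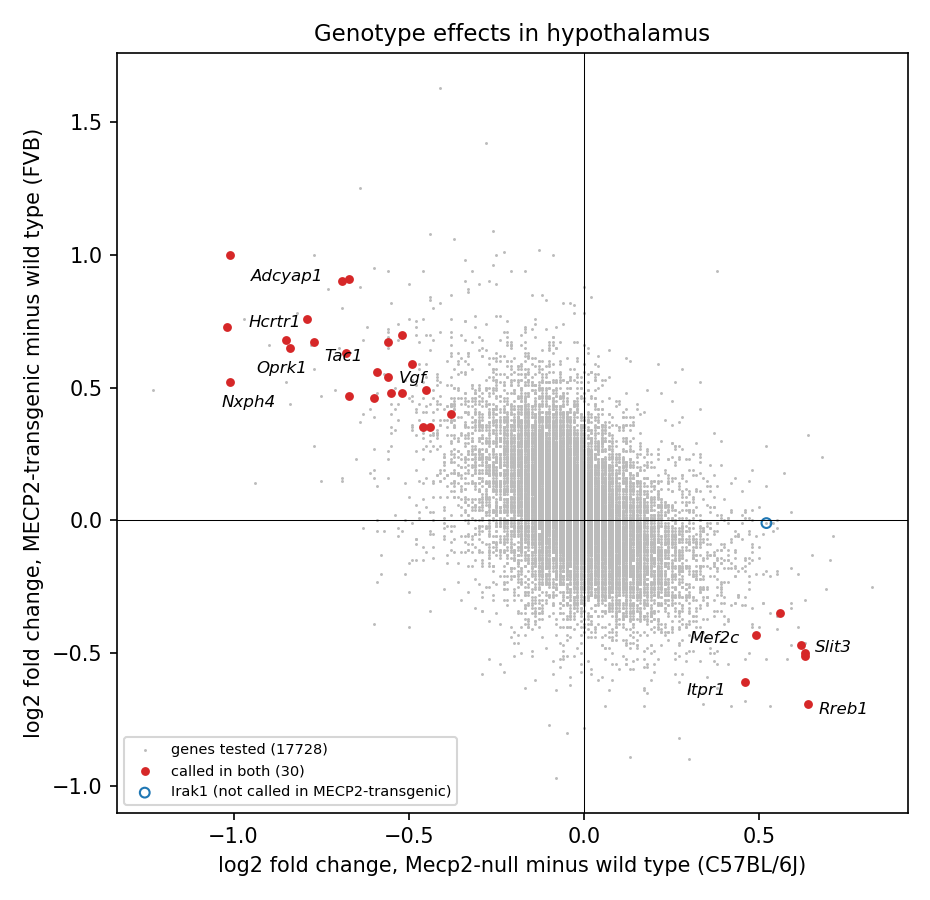
Log2 fold change of each of 17728 genes in Mecp2-null (horizontal axis) and in MECP2-transgenic mice (vertical axis), each against the wild type of its strain. The 30 genes called in both comparisons (red) all lie in the quadrants of opposite sign, 23 in the upper left and 7 in the lower right, and Irak1 (blue circle) lies at 0.52 and -0.01.

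**Figure D4:**
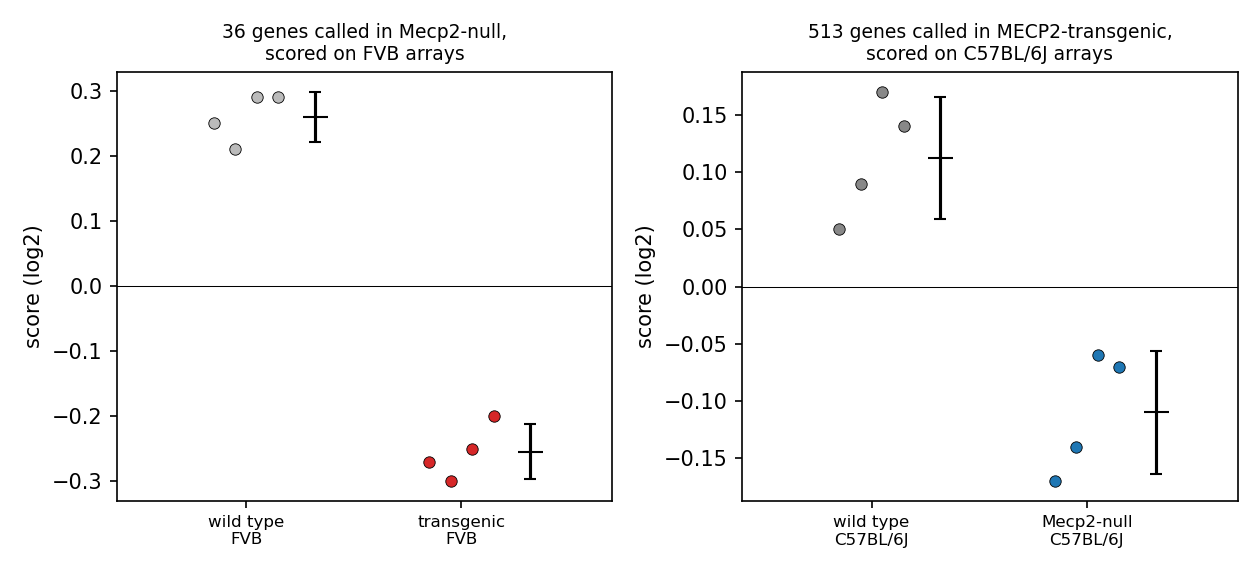
Score on each array (points, log2 scale, vertical axes) of the genes called in one strain measured on the arrays of the other strain, by group (horizontal axes), with the group mean and SD (n = 4). Transgenic arrays lie at -0.26 ± 0.04 against 0.26 ± 0.04 in their wild type, and Mecp2-null arrays at -0.11 ± 0.05 against 0.11 ± 0.05.

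The difference between the genotype effects passed for 821 genes, of which 684 were higher and 137 lower in the transgenic than in the Mecp2-null comparison (245 and 366 after centring, 332 and 323 after cyclic loess). With clone and predicted names passed over, the largest on the higher side were in Zfp874a (2.04), the radial glia fatty acid-binding protein gene Fabp7 (1.9, adjusted p = 0.0368), Pgr15l (1.77), C1ql4 (1.73, adjusted p = 0.0451) and Ssxb9 (1.7). On the lower side they were in Rreb1 (-1.34, adjusted p = 4.64e-05), the parvalbumin gene Pvalb (-1.21, adjusted p = 0.0392), Fam163b (-1.14), Slit3 (-1.14) and Hs6st3 (-1.13). Fabp7 and C1ql4 did not pass under either other scaling or without a filter on dim probe sets. Without that filter the difference in Ssxb9 was 0.53 (adjusted p = 0.185). With the stricter filter that in Zfp874a was 0.74. Sst, which passed in neither genotype in the fit used here but did under some alternatives, differed between them by 0.86 (adjusted p = 0.00609). By camera 12 of 31 lists differed, led by oligodendrocyte precursor markers (6 of 8 higher, 7 when adjusted over the list alone, adjusted p = 0.000135, and 0.172 with an estimated correlation) and neuropeptides (11 of 46 higher, 14 higher and 1 lower when adjusted over the list alone, adjusted p = 0.00102, and 0.172 with an estimated correlation). Receptor genes (8 of 44 higher and 1 lower, adjusted p = 0.00772, and 0.565 with an estimated correlation), GABA system genes (2 of 18 higher, 9 when adjusted over the list alone, adjusted p = 0.0418, and 0.565 with an estimated correlation) and cholesterol synthesis genes (3 of 20 higher, adjusted p = 0.00174, and 0.565 with an estimated correlation) also stood higher. So did microglial markers (3 of 15 higher, adjusted p = 0.00772, and 0.565 with an estimated correlation), genes of oxidative phosphorylation (0 of 44, adjusted p = 0.0328, and 0.683 with an estimated correlation) and ribosomal protein genes (0 of 51, adjusted p = 0.0215, and 0.683 with an estimated correlation). Stress and chaperone genes differed with them, all 14 above 0 with a median of 0.39 and 2 higher (adjusted p = 0.00102, and 0.565 with an estimated correlation). Ion channel genes (2 of 33 higher and 0 lower, adjusted p = 0.00174, and 0.565 with an estimated correlation) and circadian clock genes (1 of 21 higher and 1 lower, adjusted p = 0.00102, and 0.565 with an estimated correlation) stood lower. Thalamus, striatum and cortex markers stood lower (3 of 16 lower, adjusted p = 0.003, and 0.104 with an estimated correlation). No list passed with an estimated correlation in this comparison (3 had an unadjusted p under 0.05), while fry called 11. The count was 1433 without FVB wild type array 4, 541 without FVB wild type array 1, 439 and 450 without transgenic arrays 1 and 2, 424 and 438 without null arrays 1 and 2, and 405 without C57BL/6J wild type array 3 or 4. The call of Fam163b ended without any of 5 arrays in turn, and those of Fabp7, C1ql4 and Pvalb without any of 10 to 14 (adjusted p up to 0.1). With a thalamic marker score as a covariate, Fabp7 (0.0616) and Pvalb (0.148) did not pass.

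The wild types of the strains differed far more than either mutant from its control. Between FVB and C57BL/6J wild types 3367 genes passed, 396 higher and 2971 lower in FVB (1759 and 1110 after centring, 1110 and 1417 after cyclic loess). Centring moved the median log2 difference of all genes from -0.08 to 0.09. The glycerophosphodiester phosphodiesterase gene Gdpd3 was 12.3-fold higher in FVB (log2 difference 3.62, adjusted p = 9.86e-06), Catspere1 was higher by 2.82 and the serine protease inhibitor gene Serpina3n by 1.72 (adjusted p = 6.86e-08). The zinc finger genes Zfp33b (-2.83, adjusted p = 9.91e-09), Zfp951 (-2.51, but -0.77 without a filter on dim probe sets) and Zfp874a (-2.21) were lower in FVB, the last not with a stricter filter on dim probe sets (adjusted p = 0.213). The count was 1988 without C57BL/6J wild type array 3. Strain, breeding and any array batch cannot be told apart here, and a sequence difference under a probe changes its signal without a change in expression.

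Long genes and the other genes had different median changes, in opposite directions in the genotypes. In transgenic mice the median log2 change was -0.017 for 2296 genes longer than 100 kb and 0.062 for 15386 other genes, a difference of -0.08. In Mecp2-null mice the medians were -0.002 and -0.043, a difference of 0.041. Of the genes that fell in transgenic mice 35 of 63 with a known length were longer than 100 kb (55.6%), against 27 of 448 that rose (6.03%) and 13% of all genes tested. In Mecp2-null mice 6 of the 9 higher genes and 3 of the 27 lower genes were that long. Genes over 200 kb had a median of 0.03 in Mecp2-null and -0.038 in transgenic mice, and genes of 10 kb to 20 kb a median of -0.047 and 0.087. Neither difference exceeded the largest that other splits of the arrays of the same strain gave, 0.044 for C57BL/6J and 0.13 for FVB. Without C57BL/6J wild type array 3 the difference in Mecp2-null mice was 0.045, and without FVB wild type array 3 that in transgenic mice was -0.047. With a bound of 50 kb the differences were 0.016 in Mecp2-null and -0.059 in transgenic mice.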

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

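The tests of the scaling of the arrays and of Irak1 and its locus were chosen after the result was seen. The tests of shared array quality and of thalamic tissue, and all splits of the arrays, had their predictions written before. The thalamic score as a setting for the other results, unlike that prediction, was added after the data were seen.

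Single arrays lay far from the other 3 of their group in 15 of 352 tests of 88 named genes in 4 groups. Chance flags about 1 in 20 groups, here 17.6. In C57BL/6J wild type mice these were Serpina3n on array 1 (8.62, lowest) and, on array 3 and each the highest, Gdpd3 (6.71), Gprin1 (8.44) and Nlgn2 (9.77). In Mecp2-null mice they were Catspere1 (5.54, highest) and Gal (5.3, lowest) on array 1, Npy on array 2 (7.97, lowest) and Nxph4 on array 4 (6.67, highest). In FVB wild type mice they were Gprin1 on array 1 (7.78), Sdk1 on array 2 (6.42), Plch2 on array 3 (7.83), and Nts (7.1) and Prph (6.63) on array 4, each the highest, with Fhdc1 on array 4 the lowest (6.96). In transgenic mice it was Pvalb on array 3 (7.14, lowest).

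Probe sets that name no gene held a signal as well. Of 353511 above the dim bound, 21 were called in Mecp2-null mice (8 higher, 13 lower) and 47 in transgenic mice (43 higher, 4 lower). Of those called in both, 2 had opposite signs and 1 the same sign, and the r across these probe sets was -0.18.

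The first pattern is that 448 of 513 called genes were higher in transgenic mice. After centring, 45.9% of called genes were higher, and after cyclic loess 51.7%. Centring did not merely even out the calls, since the median change of all genes went from 0.05 to -0.05. Both corrections take out a shift common to most genes whatever its source. These shares therefore decide nothing about a shift or a brightness-dependent difference of the arrays. A wide rise of mRNA in transgenic tissue is not tested either, since normalized values, whose all-gene median change was 0.05, keep no total. The genotype split ranked 4 of 35 by count, with 513 genes against 1601 for the highest other split, so chance cannot be excluded for the count. The splits with 1601 and 681 genes kept 3 of the 4 arrays of each genotype and exchanged wild type array 4 for a transgenic array. Without that wild type array the genotype count was 1390, so those splits need not point away from genotype. The split with 804 genes kept only 2 arrays of each genotype, which points to structure among the FVB arrays that does not follow genotype. It set replicates 2 and 3 of both groups against replicates 1 and 4. Residuals of same-numbered FVB arrays correlated at -0.19, 0.33, 0.52 and 0.53. The structure may thus follow the replicate number, whose meaning the labels do not give. Which of these explanations holds stays open.

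The second pattern is the opposite change with loss and gain of MeCP2. With 3 residual components taken out, which hold 56.6% of the residual variance, r was -0.375, so these axes alone did not account for r. They were taken from differences within groups, so an axis of array quality that follows genotype was not removed. The test therefore cannot exclude array quality as a source of the opposite changes. The value of r was -0.633 with a thalamic marker score as a covariate (medians of 15 markers -0.19 in transgenic and 0.11 in Mecp2-null mice). The covariate has 1 slope per gene for both strains, and the markers moved in opposite directions in the mutants. Error in that slope can by itself make r more negative, so this test decides nothing about thalamic tissue. After cyclic loess r was -0.443. The spread of r was 0.044 when single arrays were left out, but such fits share most arrays, so 0.044 is not its sampling error. The size of r ranked 1 of 100 draws (0.478 against 0.464 for the highest other draw). The margin was small and only part of all pairs of splits was drawn, so chance is not excluded for r. What stays open is how much of r over all genes comes from array structure, since 1 draw of regrouped arrays gave nearly the same size. Genes called in both comparisons were not counted under regrouped arrays, so the same question stays open for them.

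The third pattern is the rise of Irak1 in Mecp2-null mice only. If it followed the dose of MeCP2 it should fall in transgenic mice to -0.26 or below under the bound that was set, but the lower bound of its change there was -0.19. Irak1 lies next to Mecp2 in the gene table, and the chance that 1 of 9 random genes, the number that rose, does so is 0.1% (0.41% for the 36 called), which may point to an effect of the altered locus on its neighbour. Of its 26 probe sets 24 were higher in Mecp2-null (median 0.54) and 14 in transgenic mice (median 0.06). The locus was looked at after Irak1 was seen, its call ended when any C57BL/6J array was left out, and the structure of the locus was not analysed here.

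Other splits were counted for the remaining results. The count of genes whose genotype effects differ, which includes genes changed in 1 genotype only, ranked 1 of 100 draws (821 against 327). Chance is thus unlikely for that count, although not every pair of splits was drawn. For the Mecp2-null count the genotype split ranked 1 of 35 (36 against 17) and for the wild types 1 of 35 (3367 against 95). That is the best rank that 35 splits allow, and ranks were not adjusted for the number of such tests. Chance is thus less likely there but not excluded by rank alone. The lists called ranked 3 of 35 in Mecp2-null (11 against 12) and 2 of 35 in transgenic mice (11 against 12), and the gene length difference 2 of 35 (0.041 against 0.044) and 8 of 35 (0.08 against 0.13), so chance is not excluded for these.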

How the results depend on the processing

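Centring, cyclic loess, the exclusion of FVB wild type arrays 3 and 4 and the thalamic covariate were chosen after the result was seen.

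No called change of a named gene turned sign under any alternative, but the balance of calls did turn. Higher and lower calls went from 448 and 65 to 169 and 199 in transgenic mice and from 396 and 2971 to 1759 and 1110 between wild types after centring, and the ion channel calls in transgenic mice from 2 higher to 3 lower. Of single values compared under the alternatives chosen beforehand, 2335 stayed the same, 568 gene calls ended, 6 genes newly passed and 19 other values moved. Under the added alternatives 394 stayed the same, 97 gene calls ended and 5 other values moved. A gene stayed the same when it kept its side of the threshold. A score stayed the same when it moved by no more than the SD of its wild type arrays. The number of genes called was 84 in Mecp2-null (19 higher, 65 lower) and 30 in transgenic mice in fits of the 8 arrays of the strain, where 62 named transgenic calls ended, against 3 with array weights, 8 to 11 with another normalization, filter or summary, 13 without FVB wild type arrays 3 and 4, 24 after centring, 27 after cyclic loess and 23 with the thalamic covariate, which also ended 1 call in Mecp2-null mice and 2 differences. The fits of 8 arrays have fewer residual degrees of freedom and their own variance. Fewer degrees of freedom alone do not account for a count that rose in 1 strain and fell in the other. Mean correlations of arrays with their own group were 0.965 to 0.977 in FVB wild type, 0.981 to 0.982 in transgenic and 0.984 to 0.988 in C57BL/6J mice. The variance shared by all groups may thus be too small for FVB and too large for C57BL/6J mice. With array weights the number of genes called was 259 in Mecp2-null and 1056 in transgenic mice, with 2140 for the difference and 119 called in both. Without FVB wild type arrays 3 and 4 it was 59 and 994. The correlation of the effects was -0.462 after quantile normalization, -0.418 without a filter, -0.458 with array weights, -0.443 after cyclic loess and -0.346 without those arrays, against 0.464 for the highest other draw of splits under the processing of the report. The gene length difference in Mecp2-null mice was 0.016 with a bound of 50 kb, 0.028 without a filter on dim probe sets, 0.051 with a stricter filter, 0.046 with 4 or more probe sets per gene and 0.045 after cyclic loess. The 0.044 of other splits was found under the processing of the report only, and no splits were run under these alternatives. With an estimated correlation camera called 0 lists in Mecp2-null and 0 in transgenic mice. Apart from the fits with fewer arrays, the cause was not tested. Leaving out 1 array at a time gave 8 to 44 genes in Mecp2-null, 126 to 1390 in transgenic mice, 405 to 1433 for the difference, 1988 to 3971 between wild types and 7 to 31 called in both, an r from -0.517 to -0.371, 7 to 14 lists in Mecp2-null mice and a length difference of 0.038 to 0.045 there and of -0.116 to -0.047 in transgenic mice. Dim probe sets limit what can be seen: 21247 genes were tested without a filter and 14114 with the stricter one. The alternatives for Mecp2 and for linear values gave no value, and the fits of 1 strain gave none for the difference or the correlation.

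With the replicate number as a block (replicate block), 89 genes were called in Mecp2-null, 1691 in transgenic mice and 2049 for the difference, with 67 called in both. Sst, called in neither genotype in the report, passed in both (0.0207 and 0.0131). Arrays of the same number had residual correlations of 0.26, -0.15, 0.27 and 0.16 in C57BL/6J and -0.19, 0.33, 0.52 and 0.53 in FVB. The array of the same number was the best partner for 1 of 4 Mecp2-null and 3 of 4 transgenic arrays. The labels do not say that mice were paired, and not every pair correlated, so the numbers were not used as pairs. The wild types of different strains have no such value.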

Other observations

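The neighbours of Mecp2, the bins by level, and the tests after centring, after cyclic loess, without FVB wild type arrays 3 and 4 and with a thalamic covariate were chosen after the result was seen.

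Of 28 glutamate system genes, Grik5 (0.45), Grin2d (0.38), Grin3a (0.43) and Grm2 (0.48) rose in transgenic mice and, named after its value was seen, the glutamine synthetase gene Glul fell by 0.2, while none passed in Mecp2-null mice (camera adjusted p = 0.547 and 0.992). Among 26 monoamine genes the serotonin receptor gene Htr1a (0.74) and the histamine receptor gene Hrh3 (0.43) rose and the dopamine receptor gene Drd3 fell by 0.4 in transgenic mice (camera adjusted p = 0.905; 0.2 in Mecp2-null mice, with no call). The neurexin gene Nrxn2 (0.24) and the neuroligin gene Nlgn2 (0.34) rose among 26 adhesion and scaffold genes (camera adjusted p = 0.63, and 0.0382 and lower after cyclic loess). In the deposited scaling the adjusted p of that list with an estimated correlation was 0.916. Grin2d, Grm2, Hrh3, Nrxn2 and Nlgn2 passed under neither other scaling, Htr1a (0.0579) and, named below, Pcdhb1 (0.064) not after centring and Drd3 (0.0512) not after loess. Of 27 earlier candidate targets Nxph4 fell and Irak1 rose in Mecp2-null mice, and Nxph4 and the protocadherin gene Pcdhb1 (0.88) rose in transgenic mice (camera adjusted p = 0.409 and 0.547). Hdac9, a histone deacetylase, fell by 0.36 among 31 chromatin genes (0.939 and 0.102), Gamt alone rose among 7 creatine genes (0.525 and 0.485), the adenylyl cyclase gene Adcy5 rose by 0.32 among 36 genes of CREB and calcium signalling (0.0883 and 0.823), and Olig1 (0.36) and the interferon-induced gene Ifit2 (0.6) rose among 18 oligodendrocyte (0.468 and 0.379) and 15 interferon response genes (0.276 and 0.634). Adcy5, Olig1 and Ifit2 passed in the deposited scaling alone. Of the transgenic calls in this paragraph all but that of Gamt ended when single arrays were left out, those of Grik5 (0.0508) and Grin2d (0.0507) only without transgenic array 2 and the others without any of 2 to 14 arrays in turn. Without a filter on dim probe sets Pcdhb1 (0.07), Ifit2 (0.0794) and Glul (0.0591) did not pass, with the stricter filter Htr1a (0.0872) and Drd3 (0.0726) did not, after quantile normalization Hrh3 (0.0615) and Ifit2 (0.0574) did not, and with the mean in place of median polish Glul (0.075) did not. Nor did Hrh3 (0.0919), Drd3 (0.0549), Pcdhb1 (0.0528) and Ifit2 (0.0868) pass without FVB wild type arrays 3 and 4, nor Grm2 (0.0508), Htr1a (0.1), Drd3 (0.174), Pcdhb1 (0.0508), Hdac9 (0.13), Nxph4 (0.0569) and Glul (0.132) with a thalamic marker score as a covariate. The CREB list stood higher in Mecp2-null mice after centring (0.0189) and cyclic loess (0.00761). In the deposited scaling its adjusted p with an estimated correlation was 0.61.

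No member passed in either genotype in the following lists, given with the camera adjusted p in Mecp2-null and in transgenic mice: GABA system (0.0974 in transgenic mice), vesicle release (0.728 and 0.941), immediate early genes (0.181 and 0.128), glucocorticoid response (0.819 and 0.372), splicing (0.76 and 0.823), hypothalamic transcription factors (0.428 and 0.64), astrocytes (0.409 and 0.823) and ependyma (0.488 and 0.372). No member passed either for oxidative phosphorylation (0.76), ribosomal proteins (0.76), microglia (0.361) and endothelium (0.76) in Mecp2-null mice, or for pituitary (0.823) in transgenic mice. These lists held some calls under alternatives. In transgenic mice without FVB wild type arrays 3 and 4, 6 splicing genes, 2 vesicle release genes, 1 GABA gene and 1 glucocorticoid response gene were higher and 1 astrocyte marker was lower, and 1 GABA gene was lower in Mecp2-null mice. After centring, and after cyclic loess, 1 splicing gene and 1 vesicle release gene were lower in transgenic mice. Medians were above 0 but camera's direction was lower for the monoamine, CREB, glucocorticoid, transcription factor, ependyma, pituitary and interferon lists in transgenic mice, where the median of all genes was 0.05. The splicing and earlier candidate lists had medians of -0.03 and -0.02 with a higher direction in Mecp2-null mice, where that median was -0.04. Of 3 blood markers Hbb-b1 was at 0.54 and -0.01, Alas2 at 0.33 and -0.1 and Slc4a1 at 0.25 and -0.21 in Mecp2-null and transgenic mice, too few to test as a list.

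Of the 40 genes tested within 20 genes on each side of Mecp2, 2 were called in Mecp2-null mice, Irak1 higher and the plexin gene Plxna3 lower (-0.49), and 4 in transgenic mice, all higher: Zfp92 (0.46), Pdzd4 (0.41), the filamin gene Flna (0.48) and Plxna3 (0.59). Among 5 bins of genes by level, the dimmest (mean level 5.45) had a median change of 0.034 in Mecp2-null and -0.057 in transgenic mice, and the brightest (9.43) one of -0.052 and 0.087. The difference between long and other genes in transgenic mice ran from 0.011 in the dimmest to -0.139 in the brightest bin.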
